A study of Cucumis sativus with 6 samples.

How the data were processed

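Total RNA of cucumber (Cucumis sativus) inbred line YB was extracted from dissected peel and flesh at 3, 6 and 9 days after self-pollination, with 3 fruits mixed in each of 6 libraries, per the labels' protocols. Per the same protocols, mRNA was isolated and ribosomal RNA removed before cDNA synthesis. TopHat, with no version, and Cufflinks 2.1.1 are named in the submitters' processing notes. The genome build, the annotation and the use of strand are not given in the sources used here, so reads of overlapping or antisense genes and of near-identical copies may be assigned to either, and 1023 of the 21317 genes shared their deposited locus with another gene.

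The deposited table gave an FPKM value per gene and library (fragments per kilobase of gene model, scaled to the mapped fragments, per the file headers). It also gave columns that the headers call counts. Their values were not whole: in each library the low values were multiples of 1 step, between 0.565 and 1.07, so they were treated as a scaled signal that the authors had made from counts before deposit. Dividing by the step gave whole numbers for 99.7% to 100% of the values (within 0.05 of a whole number), and these recovered reads served for depth and for added count tests. They summed to between 14899922 and 23740219 per library. Median ratios of the deposited count columns of each library to the geometric mean were between 0.963 and 1.02. These ratios were not taken on the FPKM, which summed to between 573006 (flesh, day 3) and 739338 (peel, day 9). The deposited scaling of the FPKM was kept. Gene names are the product descriptions of the table; 2823 genes were named only as unknown proteins, and a separate reference table whose identifiers did not match was not used here.

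Tests were run with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), so a log2 difference is on that scale and understates the change of low genes. Genes with a mean of at least 1 FPKM over the 6 libraries entered (17265). The model held tissue and day as a factor, which left 2 residual degrees of freedom, with an intensity trend for the variance and Benjamini-Hochberg adjustment, and genes were called at an adjusted p under 0.05. All limma, edgeR and DESeq2 tests were two-sided. No tissue and day had a replicate, so the spread measures how far days depart from a common tissue difference, or tissues from a common time course, and a real change of that difference counts as error. Slopes were compared in a model of tissue by day as a number, also with 2 residual degrees of freedom. Differences within 1 day or 1 tissue have no replicate check and were counted at 4-fold without a test. The precision of single values is limited by counting error, which depth sets, and by the fruits sampled, which cannot be estimated here.

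Gene lists were 26 sets of product names, of which 25 had at least 3 tested members. Each was tested with camera of limma at a preset correlation of 0.01 between genes, adjusted over the 25 lists. It was tested again with the correlation estimated from the data, and no list then passed in any of the 3 contrasts tested. With the estimate camera also refers its statistic to the 2 residual degrees of freedom, so a loss there need not come from correlation between genes. For peel against flesh the estimate was 0.41 for cuticle and wax and 0.38 for phenylpropanoid entry. It was 0.011 for defence and wounding and 0.009 for ethylene, near the preset, so the loss in these 2 lists came mainly from the degrees of freedom. The fry test of limma, which asks whether the genes of a set move on balance one way, was also run. The models, the lists, the 4-fold bound, the alternatives of each test and the rule for named genes were fixed before the data were examined. The rule took the 8 largest rises and 8 largest falls past the test with a mean of at least 5 FPKM, a product name and the same sign in every pair; from each list up to 3 members past the test with the highest mean FPKM, or the 2 most abundant where none passed; and, where no gene passed, the 4 with the smallest p in each direction. For lists without a member past the test, the examples are printed only where the list itself passed or concerns phenolic metabolism, a limit set after the data were seen. Genes chosen after their values were seen are named as such.

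Alternatives were pseudocounts of 0.1 and 5, no filter and a mean of at least 5 FPKM, upper-quartile and quantile rescaling, limma without a trend, each library left out, no day term and day as a number. Added after seeing the data were edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads, edgeR with DESeq2 size factors, the removal of genes sharing a locus, lists without each library and narrowed lists.

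The scripts were tested on simulated data with 17265 genes and 200 changed genes in 2 sizes of 100. For limma the data had the fitted means, with the tested difference set to 0 outside the changed genes, and each gene's own residual SD. That SD was estimated on 2 residual degrees of freedom and taken as true, so the shares recovered are not the power at the real spread. For peel against flesh limma recovered 41% of genes changed by 2 log2 units and 69% of those changed by 4, with 3 false calls. When every gene had the median SD, it recovered 100% and 100%, with 9 false calls. Counts for edgeR were simulated apart, around each gene's mean, with the same dispersion for every gene and no day effect. On 16802 genes of these edgeR recovered 93% and 98%, with 12 false calls. The noise differed from that given to limma, so these shares do not rank the 2 methods. For day 9 against day 3 limma recovered 12% and 54%. For the slope difference it recovered 0% of changes of 0.5 or 1 log2 unit per day with each gene's own SD, with median estimates of 0.49 and 0.98. It recovered 99% and 100% when every gene had the median SD, so the outcome depends on the spread that was set.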

Results

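RNA was sequenced from the peel and the flesh of cucumber fruits of the inbred line YB, collected 3, 6 and 9 days after self-pollination, in a study titled as a search for genes related to fruit astringency. Astringency is the drying sensation that tannins and other phenolic compounds give in the mouth. Each of the 6 libraries was a mix of 3 fruits, with 1 library per tissue and day. The table held 21317 genes, of which 17265 had a mean of at least 1 FPKM (fragments per kilobase of gene model, scaled to the mapped fragments of the library) and were tested. The reads assigned to genes numbered 20999942 in peel and 23599019 in flesh at day 3. They numbered 19067317 and 23740219 at day 6, and 14899922 and 19151955 at day 9. On the first principal component of log2(FPKM + 1), with 51.8% of the variance, the day 9 peel library lay at -124 and stood apart from the other libraries, which lay between -36.6 and 79.6.

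Peel and flesh were compared first, as the main contrast of the dissection. A pair of 3-ketoacyl-CoA synthases, which elongate the fatty acids of waxes, were higher in peel than in flesh. A germin-like protein, an ACC oxidase, which makes ethylene, and a YABBY transcription factor, of a family that sets the outer side of plant organs, were also higher in peel, by over 5 log2 units. Flesh had higher levels of the transcription factors UPBEAT1 and SUPERMAN-like, of a CONSTANS-like zinc finger protein and of Terminal flower 1, a relative of the flowering signal FT. limma called 45 genes, 31 higher in peel and 14 higher in flesh, and each of the 45 had the same sign at all 3 days. The test calls only genes whose daily differences nearly agree, so the shared sign adds no support. Their log2 differences ran from 2.49 to 8.30 in the genes higher in peel and from -2.20 to -5.36 in those higher in flesh, with standard errors of 0.16 to 0.61. Their limma adjusted p lay between 0.045 and 0.0471. The error of this comparison was the departure of each day from a common tissue difference, since no tissue and day had a second library. With any 1 of the 6 libraries left out, limma called 0 genes, with 1898 to 4202 at an unadjusted p under 0.05. Each such fit left 1 residual degree of freedom, and leaving out either library of a day gave the same estimates. The adjusted p were already near the threshold, so the loss of all calls does not show that they rest on a single library.

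Among the genes higher in peel, Germin-like protein 6 (Csa1G596420) had 440 FPKM in peel and 6.09 in flesh at day 3, and 443 and 0.945 at day 6. At day 9 it had 88.0 in peel and 0.538 in flesh, the last from 10 reads, and its log2 difference was 6.55 ± 0.46 (SE). The ACC oxidase (1-aminocyclopropane-1-carboxylate oxidase 4, Csa1G064730) was higher in peel by 5.79 ± 0.40 and the putative tryptophan synthase beta chain (Csa1G064170) by 5.42 ± 0.29. The YABBY gene (Csa3G033810) was at 143, 108 and 48.0 FPKM in peel over the 3 days and at 2.84, 0.921 and 0.837 in flesh. The 3-ketoacyl-CoA synthase Csa1G501850 had 26.5, 33.2 and 57.7 FPKM in peel and under 1 in flesh, and Csa3G144140 had 31.9, 55.4 and 61.7 FPKM in peel and under 1 in flesh. The GDSL esterase/lipase Csa3G075990 differed by 5.11 ± 0.32 and the S-like RNase Csa5G636550 by 4.88 ± 0.37. The largest difference of the 45 belonged to a gene without a product name, Csa7G037590, chosen after its values were seen. It had 814, 1818 and 1550 FPKM in peel and 6.57, 1.05 and 3.70 FPKM in flesh.

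**Figure D1:**
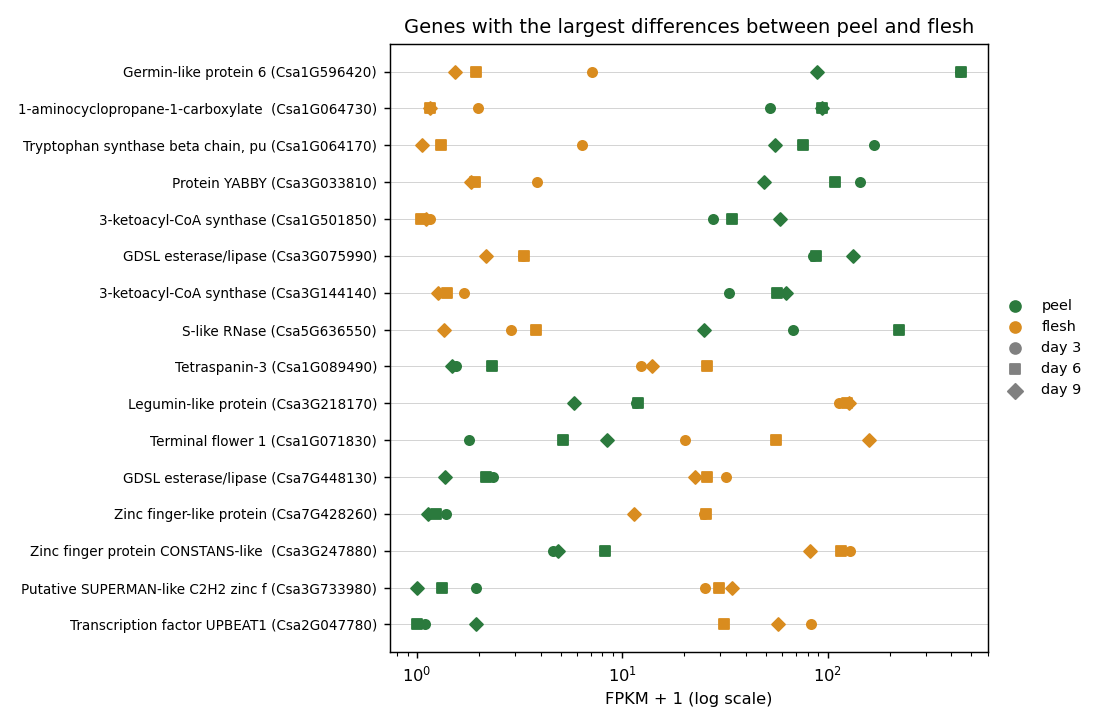
FPKM + 1 on a logarithmic axis for 16 genes with a product name past the test between peel and flesh, the 8 with the largest differences in each direction, with 1 point per library, coloured by tissue and shaped by day. In the upper 8 genes each peel point lies to the right of each flesh point, and in the lower 8 each flesh point lies to the right.

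Among the genes higher in flesh, UPBEAT1 (Csa2G047780), which regulates peroxidase genes in roots, had 81.6, 30.1 and 56.5 FPKM in flesh at days 3, 6 and 9. Its peel values rested on 1, 0 and 6 reads, and the log2 difference was -5.36 ± 0.34 (SE). The SUPERMAN-like gene (Csa3G733980) differed by -4.42 ± 0.33, the CONSTANS-like gene (Csa3G247880) by -4.23 ± 0.25, the zinc finger-like gene Csa7G428260 by -3.95 ± 0.29 and the GDSL esterase/lipase Csa7G448130 by -3.80 ± 0.20. Terminal flower 1 (Csa1G071830) had 19.2, 55.0 and 158 FPKM in flesh and 0.782, 4.15 and 7.46 FPKM in peel. Tetraspanin-3 (Csa1G089490) differed by -3.24 ± 0.21.

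The cuticle and wax list was the gene group with the highest median in peel. Of its 26 tested members, 24 had a positive difference and 2, both 3-ketoacyl-CoA synthases, passed the gene test. Adjusted over the list alone, 9 passed, all higher in peel. The list's median difference was 2.24 log2 units (camera, limma package, adjusted p = 1.38e-08; adjusted p = 0.722 with an estimated correlation). By single days its median was 0.70 at day 3, 1.99 at day 6 and 4.10 at day 9.

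The defence and wounding list (152 tested) had a median of 0.42 and a camera adjusted p in limma of 1.19e-03 (adjusted p = 0.722 with an estimated correlation). In limma 0 of its members passed the gene test, with 48 higher and 12 lower at an unadjusted p under 0.05, while edgeR called 5 higher and 1 lower. Adjusted over the list alone, 31 were higher and 7 lower. Its most abundant member, Lipoxygenase Csa2G023940, of a family that starts jasmonate and aroma synthesis, had 3904, 1497 and 2352 FPKM in peel and 436, 41.8 and 46.6 in flesh. A Major latex-like protein (Csa5G602750) had 173, 651 and 4297 FPKM in peel against 5.64, 9.70 and 5.47 in flesh.

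The ethylene list (127 tested) had a median of 0.39, and 2 members passed the gene test, both higher in peel than in flesh. These were the ACC oxidase above and Ethylene-responsive transcription factor 13 (Csa2G401240), at 26.6, 20.2 and 58.6 FPKM in peel and under 1 FPKM in flesh. Adjusted over the list alone, 20 were higher and 7 lower. The camera adjusted p in limma was 0.0223 (adjusted p = 0.722 with an estimated correlation), and it was 0.0729 without the day 6 peel library and 0.0626 without the day 6 flesh library. Single members of other lists passed the gene test. Aquaporin 2 (Csa6G445150, 2.87 ± 0.18, SE) and Gibberellin 2-oxidase (Csa4G075200, 4.18 ± 0.31), which inactivates gibberellins, were higher in peel. An Auxin-responsive protein (Csa2G200420, -3.22 ± 0.24) and a Legumin-like protein (Csa3G218170, -3.70 ± 0.29), named after a seed storage protein, were higher in flesh.

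Apart from these lists and the phenylpropanoid entry list, described with phenolic metabolism, no list passed the list test for peel against flesh. The auxin list had a median of -0.36 over 108 genes (camera, limma, adjusted p = 0.0544), the carotenoid list -0.46 over 21 and the aquaporins -0.48 over 26. The markers of other tissues or of handling had medians of -0.08 (photosynthesis), -0.06 (vascular and phloem), -0.12 (seed and ovule), 0.11 (epidermis and trichome regulators, many with trichome birefringence-like names) and 0.03 (heat shock and chaperones). Medians were -0.12 for chlorophyll biosynthesis, -0.04 for cell cycle and chromatin replication, -0.18 for cell wall loosening and pectin, and -0.13 for cellulose synthases. They were 0.02 for gibberellin, -0.23 for cytokinin, 0.14 for sugar metabolism and transport, 0.25 for triterpene and cucurbitacin genes and -0.03 for cytosolic ribosomal proteins. Some of these medians averaged opposite days. The vascular and phloem median was 0.46 at day 3, -0.13 at day 6 and -0.42 at day 9, with 15 genes at least 4-fold higher in peel at day 3 and 15 at least 4-fold lower at day 9. The photosynthesis median was 0.27 at day 3 and -0.45 at day 9. The mean differed in sign from the median for the cellulose synthases (0.10) and the heat shock list (-0.01).

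At the gene level limma found 4367 genes at an unadjusted p under 0.05, where 863 were expected by chance. On recovered reads edgeR called 264 genes, among them 40 of the 45, and DESeq2 called 3119.

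Genes of phenolic metabolism were examined because of the trait the study addressed. Phenylalanine ammonia-lyase (PAL), cinnamate 4-hydroxylase and 4-coumarate-CoA ligase turn phenylalanine into the precursors of flavonoids, tannins and lignin. Their median difference was 1.5 log2 units toward peel over 34 tested genes, and 32 of these had a positive difference. As a list they passed camera in limma (adjusted p = 3.20e-06; adjusted p = 0.860 with an estimated correlation). Their mean of 1.60 was 1.07 without the day 9 peel library or the day 9 flesh library. The gap was small at day 3 (median 0.27), 1.66 at day 6 and 2.74 at day 9, when 24 of the 34 genes were at least 4-fold higher in peel and 0 at least 4-fold lower. With neighbouring genes taken as 1 locus, the medians over 16 loci were 0.21, 0.49 and 2.00 at days 3, 6 and 9. The FPKM summed over the 16 PAL genes were 341 in peel and 292 in flesh at day 3, 509 and 52.9 at day 6, and 1232 and 113 at day 9. Those summed over the 6 cinnamate 4-hydroxylase genes were 74.6 and 65.9 at day 3, 78.5 and 34.3 at day 6, and 475 and 15.9 at day 9. The 12 ligase genes together had 223 and 124 FPKM at day 3 and 508 and 92.1 at day 9. In limma 0 of the 34 genes passed the gene test, with 16 at an unadjusted p under 0.05 and 0 when adjusted over the list alone, and edgeR also called 0.

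**Figure D2:**
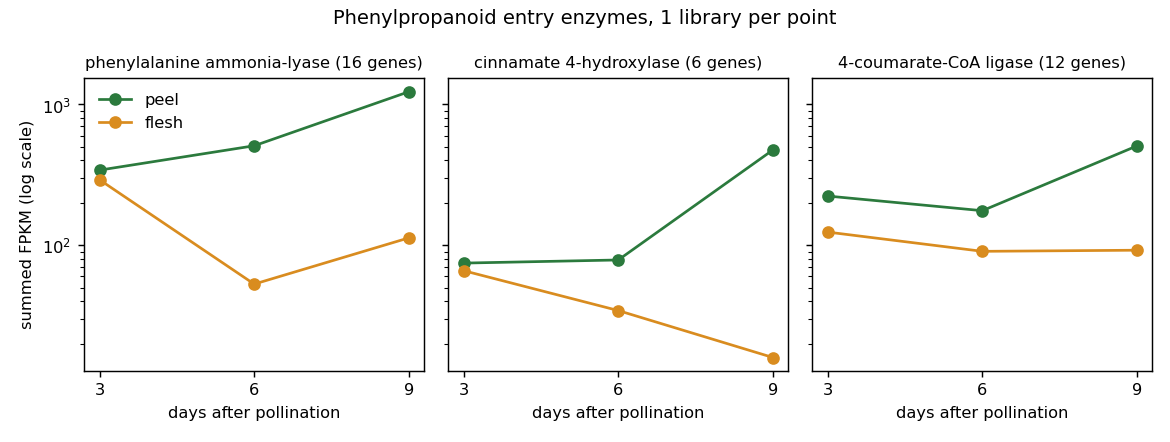
FPKM summed over the tested genes of each phenylpropanoid entry enzyme (logarithmic axis) against days after pollination, with peel and flesh as lines and 1 library per point, so no error bars. For phenylalanine ammonia-lyase the lines start at 341 and 292 FPKM at day 3 and end at 1232 and 113 FPKM at day 9.

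Many of these genes lay side by side. A group of 5 PAL genes lay on chromosome 4 between 1356382 and 1371474, and 8 lay on chromosome 6 between 20825533 and 20859732. A group of 5 cinnamate 4-hydroxylase genes lay on chromosome 2 between 5323108 and 5341747. These are positions of the table, on a genome build not given in the sources used here, as is whether starts count from 0 or 1. The most abundant PAL gene, Csa4G008250, had 114, 137 and 254 FPKM in peel and 79.2, 4.84 and 18.8 in flesh (log2 difference 2.92 ± 0.84, SE; limma adjusted p = 0.139). The 4-coumarate-CoA ligase-like gene Csa4G653450 had 109, 69.6 and 141 FPKM in peel and 71.3, 19.2 and 29.5 in flesh. The next genes were chosen after their values were seen. The cinnamate 4-hydroxylase Csa2G069200 had 20.4, 29.2 and 141 FPKM in peel and 7.51, 0.501 and 1.03 in flesh, and the ligase Csa7G430240 had 6.95, 12.4 and 134 in peel and 2.53, 0.188 and 0.941 in flesh. The cinnamate 4-hydroxylase Csa6G133710, alone at its locus, was lower in peel than in flesh at day 3 (17.4 against 43.4 FPKM) and higher at day 9 (164 against 14.0).

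The flavonoid list held enzymes further down, from chalcone synthase to the reductases that lead to anthocyanidins and proanthocyanidins. It was matched on product names and is incomplete: a gene spelled Chalcone flavonone isomerase (Csa5G221960), for example, is not in it. Of its 17 tested genes, 14 had a positive and 3 a negative difference, with a median of 0.33 and a mean of 0.64 (camera, limma, adjusted p = 0.0919; adjusted p = 0.722 with an estimated correlation). In limma 0 passed the gene test, with 4 higher and 1 lower at an unadjusted p under 0.05, and edgeR called 1. Adjusted over the list alone, 2 were higher and 1 lower in peel. The most abundant member was a Dihydroflavonol-4-reductase (Csa3G098550), at 30.7, 90.2 and 31.2 FPKM in peel and 27.2, 34 and 46.3 in flesh. A Chalcone-flavanone isomerase family gene (Csa3G002810) had 95.7, 37.3 and 1.14 FPKM in peel and 59.8, 21.5 and 4.09 in flesh, and its log2 difference of 0.06 turned to -0.10 with a pseudocount of 0.1. The next genes were chosen after their values were seen. Chalcone synthase (Csa3G600020) had 46.8, 9.55 and 6.21 FPKM in peel and 11.9, 5.28 and 0.420 in flesh, and Flavonol synthase (Csa6G040540) had 15.7, 5.83 and 4.49 FPKM in peel and under 1 in flesh. A flavonoid 3',5'-hydroxylase (Csa1G013190) had 19.5, 4.96 and 0.286 FPKM in peel and under 1 in flesh. A second Dihydroflavonol-4-reductase (Csa6G077400) was lower in peel, at 21.8, 18.1 and 6.77 FPKM against 37.3, 55.2 and 28.8 (log2 difference -1.41 ± 0.28, SE; limma adjusted p = 0.0899).

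The shikimate pathway, which supplies phenylalanine, had a median of 0.25 over 26 genes (camera, limma, adjusted p = 0.179). Its most abundant gene, Phospho-2-dehydro-3-deoxyheptonate aldolase 1 (Csa6G499800), the entry enzyme of the pathway, had 164, 218 and 643 FPKM in peel and 95.7, 25.7 and 78.6 in flesh. Shikimate kinase (Csa2G296130) had 241, 92.9 and 300 FPKM in peel and 145, 42.4 and 91.0 in flesh. The lignin and monolignol list had a median of 0.21 over 36 genes (camera, limma, adjusted p = 0.592). In it, Laccase-22 (Csa5G160220) had 153, 140 and 15.0 FPKM in peel and 188, 205 and 52.2 in flesh, and a putative Cinnamoyl-CoA reductase (Csa4G664500) had 76.6, 66.9 and 119 in peel and 60.5, 51.8 and 101 in flesh. The list of polyphenol oxidases and numbered peroxidases had a median of 0.10 over 12 genes (camera, limma, adjusted p = 0.846), with 3 higher and 2 lower in peel when adjusted over the list alone. In the shikimate and lignin lists 0 passed in limma when adjusted over the list alone, with 3 higher and 1 lower, and 6 higher and 6 lower, at an unadjusted p under 0.05, and edgeR called 0 in each. Peroxidase 31 (Csa3G829170) had 43.7, 65.8 and 32.5 FPKM in peel and 48.7, 71.8 and 74.2 in flesh, and Peroxidase 5 (Csa6G495000) had 36.1, 16.0 and 124 in peel and 16.8, 16.6 and 14.6 in flesh. Chosen after their values were seen, Peroxidase 52 (Csa6G213910) had 61.7, 10.5 and 118 FPKM in peel against 1.28, 0.216 and 0.626 in flesh, and a Polyphenol oxidase (Csa1G073640) had 21.3 FPKM in peel at day 3 and under 1 in every other library. Across these 5 phenolic lists, limma called 0 of 125 tested genes, with 42 at an unadjusted p under 0.05. By its own filter edgeR tested more members of some of these lists, and it called 3. A list of flavonoid regulators and transporters matched 0 product names and was not tested.

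The 3 days were compared singly without a test, since each tissue and day had 1 library. At day 3, 601 genes differed at least 4-fold between peel and flesh, 459 of them higher in peel. The number was 1235 at day 6 (879 higher in peel) and 1894 at day 9 (1214 higher in peel). With a pseudocount of 0.1 these numbers were 1027, 1884 and 2609, and with a pseudocount of 5 they were 204, 546 and 968. Of the 378 genes past 4-fold at both day 3 and day 6, 375 had the same sign, as did 300 of the 311 past it at both day 3 and day 9. Across genes, which are not independent replicates, the peel minus flesh difference at day 3 had a Pearson correlation of 0.706 with that at day 6 and of 0.484 with that at day 9.

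**Figure D3:**
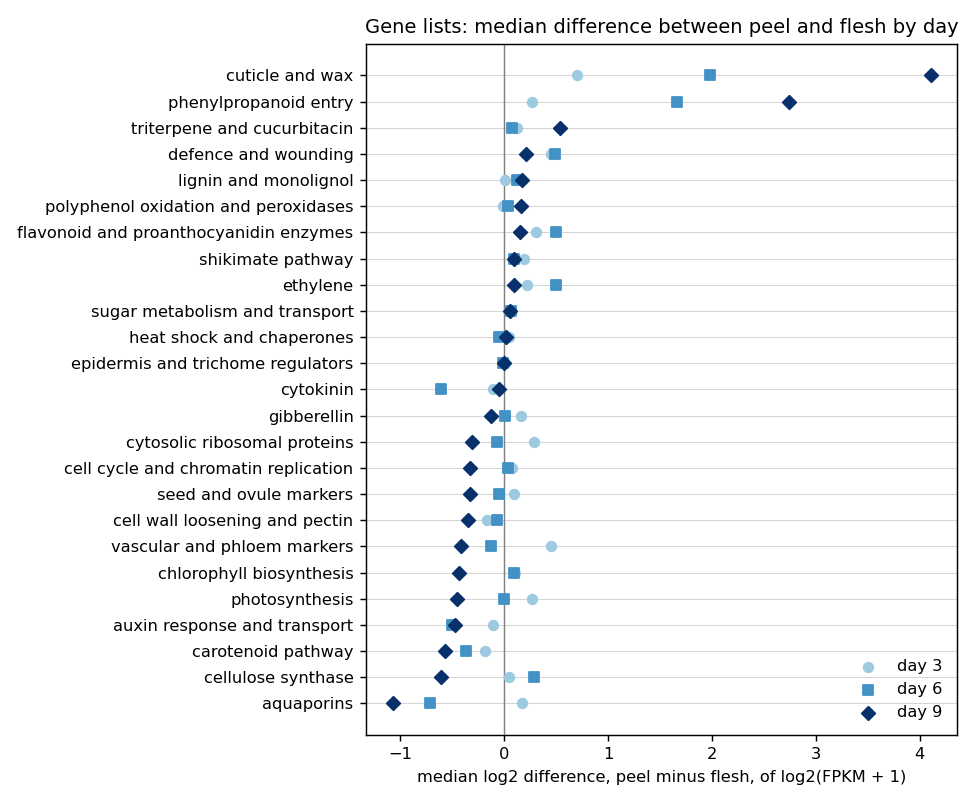
Median of the peel minus flesh difference of log2(FPKM + 1) for 25 gene lists, with 1 marker per day and 1 library per tissue and day, so no error bars. The cuticle and wax list moves from 0.70 at day 3 to 4.10 at day 9 and the phenylpropanoid entry list from 0.27 to 2.74, while the aquaporins move from 0.17 to -1.07.

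The course from day 3 to day 9 was then compared over both tissues. Genes of cell division and DNA packaging fell as a list, with a median of -1.35 log2 units over 65 genes. The photosynthesis and chlorophyll biosynthesis lists had medians of -0.94 and -0.72, and cytosolic ribosomal proteins one of -0.50. These lists passed camera in limma, and with an estimated correlation each had an adjusted p = 0.811. At the gene level limma called 0 genes for day 9 against day 3, with 4299 at an unadjusted p under 0.05 and 863 expected by chance. On recovered reads edgeR called 25 genes (18 higher at day 9) and DESeq2 2875.

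In the cell cycle list 42 of the 65 genes were lower and 2 higher at day 9 at an unadjusted limma p under 0.05, and 40 were lower and 1 higher when adjusted over the list alone. Its camera adjusted p in limma was 4.05e-10 (adjusted p = 0.811 with an estimated correlation). Histone H3 (Csa4G026900) had 1053 and 875 FPKM in peel and flesh at day 3 and 813 and 574 at day 9. Histone H2B (Csa6G193620) had 664 and 562 at day 3 and 243 and 390 at day 9. By tissue the median change of the list was -1.46 in peel and -1.10 in flesh.

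The photosynthesis list (59 genes) had 34 members lower and 2 higher at an unadjusted limma p under 0.05, and 5 lower when adjusted over the list alone. Its camera adjusted p in limma was 4.90e-09 (adjusted p = 0.811 with an estimated correlation). A Chlorophyll a-b binding protein (Csa6G139750) of the light-harvesting antenna had 301, 118 and 37.6 FPKM in peel and 527, 566 and 253 in flesh. The small chain of Ribulose bisphosphate carboxylase (Csa5G609710) had 588, 577 and 897 in peel and 217, 125 and 149 in flesh. Of the 19 chlorophyll biosynthesis genes, 9 were lower when adjusted over the list alone (camera, limma, adjusted p = 1.42e-05; adjusted p = 0.811 with an estimated correlation). Glutamate-1-semialdehyde 21-aminomutase (Csa7G067490) had 256 FPKM in peel and 154 in flesh at day 3 and 117 and 59.2 at day 9, and Protochlorophyllide reductase (Csa4G638340) had 200 and 215 at day 3 and 20.1 and 118 at day 9.

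The ribosomal protein list (152 genes) had a camera adjusted p of 3.01e-07 in limma (adjusted p = 0.811 with an estimated correlation). In limma 0 of its members passed when adjusted over the list alone, with 28 lower and 4 higher at an unadjusted p under 0.05. By tissue its median change was -0.81 in peel and -0.17 in flesh. Its mean of -0.42 was -0.19 without the day 3 peel library, -0.23 without the day 9 peel library and -0.64 without the day 3 flesh library. Its most abundant members were 40S ribosomal protein S27 (Csa5G466870), with 1360 and 1211 FPKM in peel and flesh at day 3 and 1143 and 1639 at day 9, and 60S ribosomal protein L36 (Csa3G182240), with 1197 and 921 at day 3 and 815 and 1001 at day 9.

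The aquaporins, the water channels of membranes, had a median of -1.04 from day 3 to day 9 and 6 members lower and 1 higher when adjusted over the list alone (camera, limma, adjusted p = 0.0107; adjusted p = 0.811 with an estimated correlation). By tissue the median change was -1.83 in peel and -0.14 in flesh. The mean of -0.95 was -0.40 without the day 3 peel library and -0.61 without the day 9 peel library, where the list did not pass (camera, limma, adjusted p = 0.176 and 0.167), and -1.50 without the day 3 flesh library. Aquaporin Csa6G448110 had 1868 and 2896 FPKM in peel and flesh at day 3 and 225 and 946 at day 9, and Aquaporin protein 7 (Csa5G153020) had 526 and 1220 at day 3 and 128 and 1125 at day 9.

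The vascular and phloem list (69 genes, of which 26 had phloem names, 30 WAT1-related names and 13 F-box or other names) had a median of 0.39 (camera, limma, adjusted p = 0.0343; adjusted p = 0.811 with an estimated correlation) and 1 member higher when adjusted over the list alone. By tissue the median change was -0.31 in peel and 0.98 in flesh. Its mean of 0.49 was 0.48 with the phloem-named members alone, which did not pass (camera, limma, adjusted p = 0.295). The mean was 1.07 without the day 3 peel library and 0.95 without the day 9 peel library. It was -0.10 without the day 3 flesh library (limma adjusted p = 0.949) and 0.02 without the day 9 flesh library (limma adjusted p = 0.893). Leaving out either day 6 library cannot move this mean, which rests on days 3 and 9, and the limma adjusted p was then 0.051. The phloem filament proteins Csa7G067350 and Csa7G067370 had 5752 and 3104 FPKM in peel at day 3 and 4732 and 2422 at day 9. In flesh they had 517 and 189 at day 3 and 5655 and 2507 at day 9.

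The other 19 lists did not pass for day 9 against day 3, with camera adjusted p in limma between 0.0913 (ethylene) and 0.964. The flavonoid and proanthocyanidin list had a median of -0.02 and a mean of -0.79 (camera, limma, adjusted p = 0.425). Adjusted over the list alone, 3 of its members were lower and 0 higher. Of its 17 genes, 8 were at least 2-fold lower and 2 higher in peel at day 9 than at day 3. In flesh 3 were lower and 1 higher. The phenylpropanoid entry list had a median of 0.27 (camera, limma, adjusted p = 0.276), with 1.62 in peel and -0.87 in flesh. Its mean of 0.44 was -0.45 without the day 3 peel library and -0.37 without the day 9 peel library, and it passed at 1.32 without the day 3 flesh library and at 1.24 without the day 9 flesh library.

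Single genes with the smallest p for day 9 against day 3 are given as values that did not pass the gene test in limma. Gibberellin-regulated protein Csa3G872170 had 1.21 and 3.24 FPKM in peel and flesh at day 3 and 301 and 590 at day 9. Peroxidase Csa3G736970 had 1.85 and 0.536 at day 3 and 156 and 57.4 at day 9. The Seed specific protein Bn15D14A (Csa2G010250) had 2.17 and 3.85 at day 3 and 54.6 and 73.1 at day 9, and the Metal ion binding protein Csa1G172590 had 3.51 and 1.58 at day 3 and 64.0 and 32.9 at day 9. In the other direction, Defensin D2 (Csa2G340400), an antimicrobial peptide, had 500 and 290 FPKM at day 3 and 9.34 and 2.87 at day 9. The OJ000315_02.19 protein (Csa6G319780) had 30.5 and 33.5 at day 3 and 1.2 and 0.894 at day 9. The putative Ice binding protein Csa2G223740 had 21.0 and 61.9 at day 3 and 1.46 and 5.58 at day 9, and the putative Acid phosphatase 1 (Csa2G000720) had 25.2 and 36.5 at day 3 and 1.2 and 1.95 at day 9. The limma adjusted p of these 8 genes lay between 0.0514 and 0.0564. On recovered reads edgeR called 7 of them, each at an adjusted p of 0.0432, with Acid phosphatase 1 as the exception.

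The steps between neighbouring days had no gene past the test in limma. For day 6 against day 3, 1219 genes had an unadjusted p under 0.05, and edgeR called 0 and DESeq2 301. For day 9 against day 6, 3577 genes had an unadjusted p under 0.05, and edgeR called 0 and DESeq2 2000. At least 4-fold changes between day 3 and day 9 were seen in 1697 genes in peel (898 higher) and 1115 in flesh (587 higher). Of the 493 genes past 4-fold in both tissues, 466 moved the same way.

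Whether peel and flesh changed at different rates was tested as the difference of their slopes over days. As lists, cuticle and wax genes rose in peel relative to flesh by a median of 0.29 log2 units per day and phenylpropanoid entry genes by 0.45, while vascular and phloem genes fell in peel relative to flesh, with a median of -0.30. These lists passed camera in limma, and with an estimated correlation their adjusted p were 0.376, 0.388 and 0.388. For single genes limma called 0, with 1505 at an unadjusted p under 0.05 and 863 expected by chance, edgeR called 0 and DESeq2 354. Of 9 lists past camera, 1, cuticle and wax, also passed the fry test of limma (adjusted p = 0.0301). For peel against flesh and for day 9 against day 3 fry passed 0 lists, with smallest adjusted p in limma of 0.171 and 0.224.

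In the cuticle and wax list (camera, limma, adjusted p = 7.01e-12; adjusted p = 0.376 with an estimated correlation) 7 of 26 genes had a higher slope in peel when adjusted over the list alone. Its most abundant member, Non-specific lipid-transfer protein Csa3G728130, chosen after its values were seen, had 221, 1060 and 3712 FPKM in peel and 42.0, 37.6 and 4.23 in flesh. Fatty acyl-CoA reductase Csa6G151810, of a family that makes wax alcohols, had 0.285, 7.06 and 178 FPKM in peel and 3.11, 0.506 and 0.341 in flesh. The phenylpropanoid entry list passed camera in limma (adjusted p = 1.70e-08, and 0.388 with an estimated correlation of 0.16), with neighbouring genes counted singly. In limma 0 of its 34 genes passed when adjusted over the list alone, with 12 higher and 2 lower at an unadjusted p under 0.05. Its mean slope difference of 0.38 was 0.15 without the day 3 flesh library (limma adjusted p = 0.0846), 0.20 without the day 9 peel library and 0.60 without the day 9 flesh library.

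In the vascular and phloem list (camera, limma, adjusted p = 7.01e-12; adjusted p = 0.388 with an estimated correlation) 21 of 69 genes had a lower slope in peel when adjusted over the list alone. The mean slope difference of -0.23 was -0.15 without the day 3 peel library and -0.38 with the phloem-named members alone. The WAT1-related protein Csa2G042770, of a transporter family, chosen after its values were seen, had 75.2, 35.5 and 14.2 FPKM in peel and 522, 1097 and 1536 in flesh.

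Of the single genes with the smallest p for the slope difference, 0 passed the gene test in limma. A putative Cytochrome P450 (Csa5G153010) had 0.748, 26.8 and 355 FPKM in peel and 2.50, 1.39 and 0.387 in flesh (limma adjusted p = 0.155). CASP-like protein 5 (Csa3G151500) had 2.71, 36.8 and 283 in peel and under 1 in flesh, and the IDA-like protein Csa6G484020 had 1.92, 4.40 and 15.2 in peel and 10.2, 3.94 and 0.686 in flesh. In the other direction, a putative Carbonic anhydrase (Csa1G120470) had 93.6, 12.6 and 0.432 FPKM in peel and under 1 in flesh, and the putative 14 kDa proline-rich protein DC2.15 (Csa3G027200) had 164, 10.5 and 0.625 in peel and under 1 in flesh. Flavanone 3-hydroxylase (Csa3G002800), a flavonoid enzyme, had 100, 10.7 and 0.516 in peel and 1.2, 1.39 and 0.418 in flesh. The Cellulose synthase-like protein Csa3G141890 had 49.9, 35.6 and 30.9 in peel and 11.9, 36.4 and 162 in flesh.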

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

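Of the tests in this part, the collapse of phenylpropanoid genes to loci and the lists without a library were chosen only after the result was seen. The edgeR count and the narrowed list, which is among the alternatives for vascular and phloem genes, were also added after the data were seen. For 9 gene lists the change per day differed between peel and flesh by camera in limma. None of the 9 passed camera with an estimated correlation, where their adjusted p ran from 0.376 to 0.756. The estimate was -0.034 for cuticle and wax, -0.040 for the carotenoid pathway and 0.006 for auxin. These are under the preset of 0.01, so a higher correlation was not the cause in those lists. In the rest it was between 0.023 (photosynthesis) and 0.48 (ribosomal proteins), and the cause was not tested.

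The adjusted p was 7.01e-12 for cuticle and wax (higher slope in peel), and over 9 alternatives other than the estimated correlation its highest was 1.01e-05. It was 1.70e-08 for phenylpropanoid entry, with a highest of 0.0846 without the day 3 flesh library, where the mean of 0.38 was 0.15. It was 7.01e-12 for vascular and phloem genes (lower slope in peel), with a highest of 3.92e-03. It was 1.17e-04 for photosynthesis (median -0.12 per day), with 0.0645 without day 3 flesh and 0.206 without day 9 peel, where the mean of -0.11 was -0.10 and -0.07. It was 1.20e-05 for aquaporins (median -0.22), with 0.132 without day 3 peel and 0.0586 without day 3 flesh, where the mean of -0.20 was -0.09 and -0.17, and it was -0.31 without day 9 peel. It was 2.21e-05 for cytosolic ribosomal proteins (median -0.11), with 0.191 without day 3 flesh and 0.904 without day 9 peel, where the mean turned to 0.0306 and 0.0022. It was 0.0345 for the carotenoid pathway (median -0.07), with 0.109 without day 3 peel, 0.306 without day 3 flesh, 0.344 without day 9 peel and 0.077 without day 9 flesh, and means of -0.07 to -0.14 with a library left out. It was 0.0191 for auxin response and transport (median -0.04), with 0.249 without day 3 peel, 0.0846 without day 3 flesh, 0.0503 without day 6 peel and 0.0592 without day 9 flesh, and means of -0.04 to -0.10 with a library left out. It was 0.0432 for the 6 triterpene and cucurbitacin genes (median 0.10), with 0.156 without day 3 peel, 0.0586 without day 3 flesh, 0.0556 without day 6 flesh, 0.207 without day 9 peel and 0.609 without day 9 flesh, and means of 0.09 to 0.20 with a library left out.

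More genes differed 4-fold between peel and flesh at day 9 (1894) than at day 3 (601). The day 9 peel library had the fewest reads, but with every library thinned to its depth the ratio of day 9 to day 3 was 2.95 (1900 against 644 genes). The 50 most abundant genes held between 7.33% (peel, day 9) and 9.48% (flesh, day 9) of the reads of each library, so a few genes did not take most of the fragments. Without them and with the rest rescaled, the ratio was 3.13, which so small a share had little room to change. Further separation of the tissues as the fruit grows may account for the rest, a biological hypothesis that the design cannot test, because each tissue and day had 1 library and a property of the fruits mixed for the day 9 peel stays open.

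The phenylpropanoid entry genes were higher in peel at day 9, and many of them are neighbours whose near-identical reads could have been split among copies. Collapsed to 16 loci, their median difference at day 9 was 2.00 log2 units (interquartile range 0.20 to 3.29), with 10 loci above 1 and 14 above 0, but at day 6 it was 0.49, against 1.66 over genes. The sum over the 16 tested PAL genes, which a split of reads among copies leaves as it is, was 509 FPKM in peel and 52.9 in flesh at day 6. At day 9 it was 1232 and 113. PAL as a whole thus differed on both days, but a sum does not tell how many copies did. The locus values argue against reads shared among neighbours as the whole cause at day 9. The gap over genes at day 6 rests largely on groups of neighbours, and a difference in the fruits mixed for 1 library stays open.

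Vascular and phloem genes had a lower slope in peel than in flesh, and a changing share of vascular tissue in the dissected pieces may be the source. The 26 phloem-named members had a median slope difference of -0.43 and the 30 WAT1-named members one of -0.30, while the 13 F-box and other members had one of -0.00, with 7 negative. The phloem minus WAT1 difference was -0.13 (two-sided permutation p = 0.0726, 100000 resamples). The permutation shuffled names among genes, which come from the same libraries and are not independent replicates. A change in tissue share and a regulated change could each move these name groups alike or unequally. The comparison therefore cannot tell these causes apart, whatever its p. The most abundant members, phloem filament proteins, went from 517 to 5655 FPKM in flesh (Csa7G067350) and from 189 to 2507 (Csa7G067370).

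For the 45 genes between peel and flesh, 1 of the 10 splits of the 6 libraries into 3 and 3 gave as many genes, which was the real one, and the highest other split gave 0. With 10 splits the share is never under 0.1, so the splits are too few for a share under 0.05. The other splits also leave the real tissue difference in their error, so their 0 calls say little about the 45. For the slope difference the real count in limma was 0, with 1505 genes at an unadjusted p under 0.05 and 0 called by edgeR, so 10 of 10 splits gave as many whatever the data, and this count decides nothing.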

How the results depend on the processing

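The count tests, the removal of shared loci, the lists without a library and the narrowed lists were chosen only after the data were seen; causes were not tested. The count of 45 genes between peel and flesh became 167 with a pseudocount of 0.1, 0 with 5, 0 with no filter, 209 with quantile normalization, 0 without a trend, 120 with no day term and 475 with day as a number. It became 264 with edgeR, 291 with DESeq2 size factors in edgeR and 3119 with DESeq2, and 0 to 0 with a library left out. The count was 45 at a mean of at least 5 FPKM (38 of them among the 45), 48 with upper-quartile rescaling and 44 without shared loci; with no day term 29 of the 120 were among the 45. For day 9 against day 3 the count of 0 became 4 with a pseudocount of 0.1, 8 at a mean of at least 5 FPKM, 4 with quantile normalization, 320 with a slope over day, 25 with either edgeR scaling and 2875 with DESeq2. DESeq2 called 301 genes for day 6 against day 3, 2000 for day 9 against day 6 and 354 for the slope, where edgeR called 0 for each. Genes past 4-fold numbered 1027 (day 3) and 1884 (day 6) with a pseudocount of 0.1, and 204, 546 and 968 (days 3, 6 and 9) with 5. With an estimated correlation 0 lists passed in each contrast; with a library left out 3 to 8 passed for peel against flesh (8 without either day 3 library), 5 to 8 for day 9 against day 3 and 5 to 9 for the slope (5 without day 3 flesh).

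With a library left out, the mean for day 9 against day 3 ran from -0.45 to 1.32 for phenylpropanoid entry and from -0.10 to 1.07 for vascular genes, and the slope of ribosomal proteins from -0.22 to 0.0306. For peel against flesh Csa3G098550 ran from -0.19 to 0.77, Csa6G133710 from -1.01 to 1.35 and Csa3G002810 from -0.29 to 0.72; the last was -0.10 with a pseudocount of 0.1, -0.00079 with edgeR and -0.0355 with DESeq2. For day 9 against day 3 Csa4G008250 ran from -2.24 to 1.36, Csa4G653450 from -1.14 to 0.26, Csa3G098550 from -0.28 to 1.05, Csa3G182240 from -0.52 to 0.0881, Csa5G609710 from -0.44 to 0.51 and Csa5G466870 from -0.20 to 0.39. Csa5G609710 was -0.0894 with upper-quartile rescaling, -0.25 with quantile normalization, -0.0795 with edgeR, -0.0480 with DESeq2 size factors and -0.0485 with DESeq2. Csa5G466870 was -0.0342, -0.42, -0.21, -0.18 and -0.18 under the same settings. The slope of Csa4G008250 ran from -0.40 to 1.45. Of the other values of named genes, 1218 kept direction and side of the threshold, 198 became weaker and 87 stronger. Upper-quartile rescaling moved the median of all genes for day 9 against day 3 from 0.01 to -0.11. Depth limits values under 1 FPKM, many of which rest on few reads.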

Other observations

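The count tests named in this part were chosen only after the data were seen. On recovered reads edgeR called 25 genes for day 9 against day 3, where limma called 0 with 4299 at an unadjusted p under 0.05. The following were chosen after their values were seen. A Putative lipid transfer protein (Csa4G146250) had 0.637, 8.48 and 407 FPKM in peel at days 3, 6 and 9 and under 1 in flesh. A Short-chain dehydrogenase/reductase (Csa5G072680) had 0.780, 6.37 and 117 in peel and under 1 in flesh. Lipoxygenase Csa2G028480 went the other way, at 594, 117 and 30.0 FPKM in peel and 2.67, 0.572 and 0.108 in flesh. A pair of RNA-dependent RNA polymerases, enzymes of RNA silencing, were higher at day 9 in both tissues: Csa5G544050 had 0.666 and 0.803 FPKM in peel and flesh at day 3 and 13.6 and 24.6 at day 9, and Csa5G564290 had 0.387 and 0.524 at day 3 and 12.9 and 15.2 at day 9.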
